A study of Mus musculus with 6 samples.

How the data were processed

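RNA from heart lysates of mice aged 4 weeks was measured in 6 libraries, 2 each of Cnot3 RIP, control IgG RIP and Input. The authors deposited 1 table with a value per gene symbol and library. The deposited values are CPM: each library sums to the scale of that unit with Rn45s included. Per the submitters' processing notes, the tools used were CASAVA 1.8, FastQC, Bowtie2 2.2.5, TopHat2 2.1.0 and edgeR, with the mm10 genome. The read counter, the gene annotation, the library kit and the strand setting of the counting are not given in the sources used here. Groups and replicate numbers came from the sample labels, and each column of the table was matched to its sample by name.

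The smallest step between low values gave what 1 read is worth in each library, 0.0299 to 0.0636 CPM, and with it 100% of the values were whole reads within 0.01 read (largest deviation 1.60e-04). The recovered totals were 18032715 and 17283203 in control IgG RIP, 19176056 and 25567544 in Cnot3 RIP and 15713318 and 33479580 in Input. Between 11431 and 13021 genes had at least 10 reads per library. The 10 most abundant genes took 75.7% and 72.1% of the reads in control IgG RIP, 65.9% and 63.8% in Cnot3 RIP and 84.5% and 84.9% in Input. A count of 0 allows up to 3 reads, which is 0.0899 to 0.277 scaled CPM depending on the library, and binomial intervals are exact Clopper-Pearson intervals at 95%. Such floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

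The design fixed before the data were examined named edgeR's quasi-likelihood test for counts. Because the deposited unit turned out to be CPM, limma took its place and the quasi-likelihood test on the recovered reads became an added alternative, which called 242 genes higher and 54 lower in Cnot3 RIP against control IgG RIP. CPM were scaled with TMM factors computed from the recovered reads (edgeR 4.0.16), and log2 of scaled CPM plus 0.25 was fitted with limma 3.58.1 (trended empirical Bayes) in R 4.3.3. All 6 libraries entered 1 fit with 3 group means and no block, which left 3 residual and 6.24 prior degrees of freedom. Genes were kept with edgeR's filterByExpr at a minimum count of 10, here 0.538 CPM in at least 2 libraries, which left 13010 of 24421. Fold changes are on the scale of log2 of scaled CPM plus 0.25 and understate the changes of low genes. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05, and a count with at least 2-fold change was also taken. With 2 libraries against 2, an exact permutation test of a single gene cannot give a p under 0.333, so single genes have only the limma p.

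Gene lists were tested with camera (limma) at a preset correlation of 0.01 for lists with at least 5 tested members, adjusted over the lists of a comparison, and again with a correlation estimated per list. None of the calls of any list in the 3 comparisons held with an estimated correlation. The lists, fixed before the data were examined, were CCR4-NOT subunits, mRNA decay and poly(A) factors, autophagy, p53 pathway and cell death, sarcomere, ion channels and calcium handling, nuclear-encoded respiratory chain, cytosolic ribosomal proteins, fatty acid and glucose metabolism, immediate-early and AU-rich-element mRNAs, fetal and hypertrophy genes, cell cycle, replication-dependent histones, nuclear and small noncoding RNAs, and markers of endothelium, fibroblasts, smooth muscle and pericytes, leukocytes, erythroid cells and platelets, and nerve, fat, epicardium and skeletal muscle. Lists by symbol were zinc finger genes named Zfp, snoRNA and scaRNA genes, microRNA host entries, mitochondrial ribosomal proteins and solute carriers. The microRNA host entries were all symbols that start with Mir and a digit. They include microRNA genes such as Mir208b and also Mir6236, while a host gene such as Myh7 is not among them. Mitochondrially encoded genes had no entries in the table used here, so that list gave no result. Some genes belong to more than 1 list, such as Zfp36, Myh7 and Acta1.

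Named genes followed a rule fixed before the data were examined. Against control IgG RIP these were Cnot3, Atg7, Trp53 and Pdk4 and up to 10 higher and 10 lower genes with the largest log2 fold change among those past the threshold, with a mean of at least 10 CPM in the higher group and no overlap between the groups' values. Against Input up to 8 in each direction were named by the same filters, and in each list up to 4 members of smallest p. Among the genes higher in both comparisons, the 8 with the largest smaller fold change that passed these filters were named. Genes with placeholder symbols (of the forms Gm, Rik, LOC, BC, AI, AW, AA, Mir, Snor or ending in -ps) were only counted, except Mir208b, which was named after its value was seen. Scarna10 and D5Ertd579e do not have these forms and were named by the rule. Other members named because few passed, such as Hist3h2a, Lyz2 and Pan2, fall under the same rule of smallest p.

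Coordinates and transcript features came from GENCODE M21 on GRCm38, the assembly of mm10, with 12926 of 13010 tested symbols (99.4%) matched. For 12349 of 12412 protein-coding genes (99.5%) the longest coding transcript had a usable 3′ UTR. Correlations and sequence searches used numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Reads shared by gamma protocadherins, Mir208b and Myh7, overlapping or antisense genes, and reads of ribosomal RNA in Rn45s, Lars2 and Mir6236 cannot be separated, and these values are uncertain.

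The fit was tested on simulated counts for Cnot3 RIP against control IgG RIP over 13010 genes, with 200 genes changed in each of 5 simulations. It recovered 34 of 335 genes changed 2-fold (10.1%), 259 of 335 changed 4-fold (77.3%) and 308 of 330 changed 8-fold (93.3%), with 45 calls among 63850 unchanged genes. Lists of 40 genes planted at 2-fold were called in 5 of 5 simulations and unchanged lists in 0. Genes were drawn independently of one another there, so these simulations cannot show how often lists with correlated members are called falsely. A planted heptamer with a difference of 0.2 on the log2 scale, tested over 12349 mRNAs, ranked 10 or better in 18 of 20 trials. That difference is larger than the 0.157 of the heptamer that ranked first in the data. The trials, which permuted the other values among mRNAs, do not show how smaller differences rank.

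Alternatives were RLE size factors, library size only and upper quartile scaling, no filter and a stricter one (mean CPM 5), DESeq2 1.42.0, edgeR's exact test, limma-voom, robust empirical Bayes, fits of only the 2 groups compared, a replicate block, an adjusted p of 0.10 and leaving out each library in turn. Where a group was left with 1 library, that library was assumed to vary like the other groups. Overlaps of calls between comparisons that share libraries were set beside 50 simulations with no effect.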

Results

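RNA was sequenced from heart lysates of C57BL6/J mice at 4 weeks of age in 6 libraries. Cnot3 is a subunit of the CCR4-NOT complex, which shortens the poly(A) tails of cytoplasmic mRNAs. RNA immunoprecipitation (RIP) recovers the transcripts that come down with a protein when an antibody pulls it out of a lysate. The libraries came from 2 immunoprecipitates with an antibody against Cnot3 (Cnot3 RIP), 2 with a control antibody (control IgG RIP) and 2 of the lysate itself (Input). The deposited table gave each library in CPM, reads per gene scaled to the same library total, for 24421 gene symbols. These values held whole reads, with totals from 15713318 reads in Input replicate 1 to 33479580 in Input replicate 2. Most reads belonged to Rn45s, the ribosomal RNA precursor, at 52.1% ± 1.39 (SD, n = 2) in Cnot3 RIP, 59.8% ± 0.609 in control IgG RIP and 78.8% ± 0.647 in Input. Without Rn45s the depth was 8999040 and 12500739 reads in Cnot3 RIP, 7172223 and 7023051 in control IgG RIP and 3407528 and 6954079 in Input. Ttn, which encodes the giant sarcomere protein titin, took 9.32% and 6.42% of the reads in control IgG RIP, 6.39% and 7.23% in Cnot3 RIP and 1.73% and 1.67% in Input. The labels do not state whether replicates came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

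The replicate libraries of each group resembled each other to a similar degree. Pearson's r of log2 values across genes was 0.971 in control IgG RIP, 0.965 in Cnot3 RIP and 0.975 in Input, and the SD of the log2 difference per gene was 0.50, 0.59 and 0.47. Control IgG RIP replicate 2 and Cnot3 RIP replicate 1 were closer to each other, with r = 0.975 and an SD of 0.45, than the libraries of any group were, and the closest of all 15 pairs. Genes are not independent replicates, so these values describe the libraries only.

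The comparison of Cnot3 RIP with control IgG RIP asked which transcripts the Cnot3 antibody recovered beyond the background of the procedure. Transcripts of Nfkbia, which encodes the inhibitor of NF-kappaB, stood at 372 ± 234 scaled CPM (SD, n = 2) in Cnot3 RIP and 11.9 ± 1.75 in control IgG RIP, a 27.5-fold difference (log2 fold change 4.78, SE 0.45, limma adjusted p = 0.00783). Id1, which encodes an inhibitor of basic helix-loop-helix transcription factors, was 23.5-fold higher, at 119 ± 93.9 against 3.99 ± 0.830 scaled CPM. Edn1, the precursor of the vasoconstrictor endothelin, was 18.9-fold higher and Dusp1, a phosphatase that switches off MAP kinases, was 16.3-fold higher. On the other side, transcripts of Pcdhga9, a member of the gamma protocadherin cluster of cell adhesion genes, stood at 6.72 ± 0.565 scaled CPM in Cnot3 RIP and 34.7 ± 19.3 in control IgG RIP, 0.216 of the control level (log2 fold change −2.21, SE 0.40, limma adjusted p = 0.0350). Of 13010 genes tested with limma, 200 were higher and 36 lower in Cnot3 RIP at an adjusted p under 0.05, and all of these differed by at least 2-fold.

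The other genes with the largest enrichment under the naming rule were of several kinds. Ddit4, a stress-induced inhibitor of mTOR signalling, had a log2 fold change of 4.05 (SE 0.74, limma adjusted p = 0.0350), with 325 ± 343 scaled CPM (SD, n = 2) in Cnot3 RIP and 13.1 ± 3.15 in control IgG RIP. D5Ertd579e was the most abundant of them, at 1503 ± 966 against 85.1 ± 9.34 scaled CPM, or 15.7-fold. G0s2, an inhibitor of triglyceride lipolysis, was 14.2-fold higher at 97.2 ± 97.6 against 4.63 ± 0.757 scaled CPM, and F3, which encodes tissue factor of the clotting cascade, was 13.3-fold higher at 98.2 ± 82.0 against 5.73 ± 0.292. Zfp36, which encodes tristetraprolin, a protein that binds AU-rich elements and brings CCR4-NOT to mRNAs, was higher at 188 ± 162 against 12.2 ± 0.456 (log2 fold change 3.59, SE 0.55, limma adjusted p = 0.0246). Id3, a relative of Id1, was 10.7-fold higher at 89.3 ± 84.6 against 6.14 ± 1.83. The size of these changes depended on the Cnot3 RIP library. Without replicate 1 the log2 fold changes of Nfkbia, Id1, Edn1, Ddit4, Dusp1, D5Ertd579e, G0s2, F3, Zfp36 and Id3 were 5.48, 5.47, 4.98, 5.44, 4.65, 4.70, 5.11, 4.72, 4.61 and 4.59. Without replicate 2 they were 4.10, 3.65, 3.49, 2.67, 3.42, 3.28, 2.56, 2.76, 2.57 and 2.26, and Ddit4 no longer passed (limma adjusted p = 0.0566). Without control IgG RIP replicate 1, where 0 of these genes passed limma, Edn1 had 3.59. Without control IgG RIP replicate 2 Edn1 had 4.85, and Ddit4, G0s2, F3, Zfp36 and Id3 did not pass, with limma adjusted p of 0.113, 0.0723, 0.0521, 0.0669 and 0.0679. In the mm10 genome these genes lie apart from one another, Nfkbia at chromosome 12, 55489410 to 55492647 on the minus strand, Id1 at chromosome 2, 152736251 to 152737410 on the plus strand, Edn1 at chromosome 13, 42301476 to 42307990 on the plus strand, and Zfp36 at chromosome 7, 28376784 to 28380253 on the minus strand, all annotated as protein-coding. The remaining genes by this rule were Ddit4 at chromosome 10, 59949669 to 59951834, Dusp1 at chromosome 17, 26505590 to 26562128, D5Ertd579e at chromosome 5, 36600485 to 36696024, G0s2 at chromosome 1, 193272161 to 193273217, F3 at chromosome 3, 121723537 to 121735048, and Id3 at chromosome 4, 136143497 to 136145755.

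**Figure D1:**
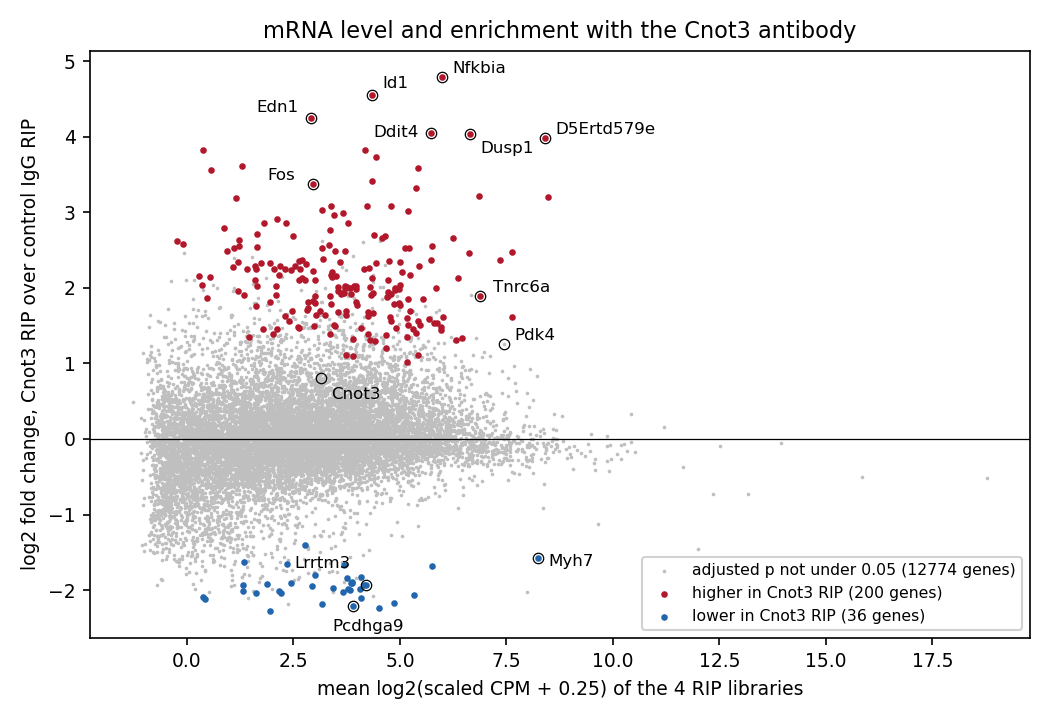
Each point is 1 of 13010 genes, with the mean log2 of scaled CPM plus 0.25 over the 4 immunoprecipitation libraries on the horizontal axis and the log2 fold change of Cnot3 RIP over control IgG RIP on the vertical axis. Red points are the 200 genes that were higher, blue points the 36 that were lower and grey points genes that did not pass an adjusted p of 0.05, with 13 genes named in the text circled.

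**Figure D2:**
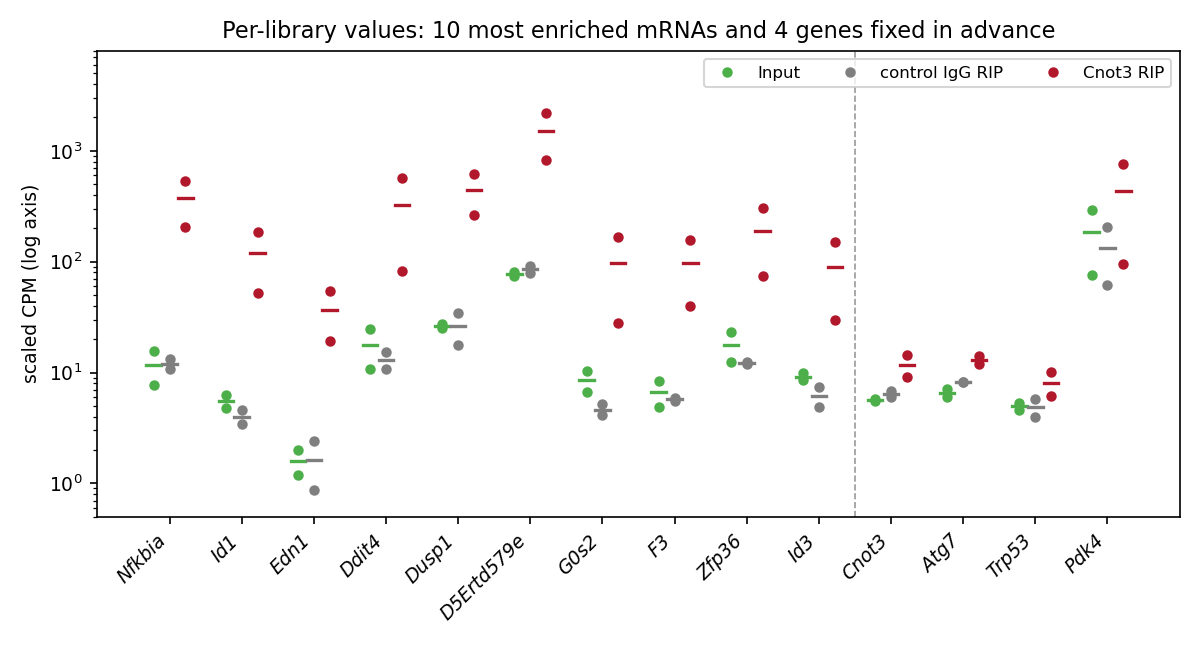
Scaled CPM on a log axis in each of the 6 libraries, with Cnot3, Atg7, Trp53 and Pdk4 right of the dashed line. Left of it are the 10 most enriched genes by the naming rule. It asked for an adjusted p under 0.05, a mean of at least 10 CPM in Cnot3 RIP, no placeholder symbol and no overlap with control IgG RIP. Points are libraries and bars are the means of 2. The Cnot3 RIP libraries lie above the other 4 for all 10 enriched genes, which the rule had fixed for the control IgG RIP libraries. For Pdk4 the Cnot3 RIP libraries stand at 94.9 and 768 scaled CPM with values of other groups between them.

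Immediate-early genes and other mRNAs with AU-rich elements, which are transcribed quickly after a stimulus and are short-lived, formed the list with the largest enrichment. Of 45 tested members, 20 were higher in Cnot3 RIP than in control IgG RIP and 0 lower in the limma test (32 and 0 adjusted over the list alone), and 43 had a log2 fold change above 0, with a median of 1.64. Besides Nfkbia and Dusp1, the members with the smallest p were Cyr61, which encodes a matricellular protein (log2 fold change 3.33, SE 0.41), and Dusp6, a phosphatase of ERK kinases (2.70, SE 0.33), each with a limma adjusted p of 0.0133. The list was higher as a set (camera adjusted p = 8.79e-27), with adjusted p = 0.669 with an estimated correlation. The list of mRNA decay and poly(A) factors held 10 of 35 members that were higher and 0 lower (16 and 1 adjusted over the list alone), with a median of 0.62. The decay factor list had a camera adjusted p = 3.77e-08, and adjusted p = 0.688 with an estimated correlation. Its leading members were Tnrc6a, which links Argonaute proteins to CCR4-NOT, at 229 ± 42.8 against 61.5 ± 5.20 scaled CPM (SD, n = 2) or 3.70-fold, Zfp36l1 and Zfp36l2, relatives of Zfp36, at 5.75-fold and 4.07-fold, and Btg2, which binds the CCR4-NOT deadenylases, at 8.09-fold.

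Genes of the p53 pathway and cell death were higher as a set, with a median log2 fold change of 0.37 and 4 of 41 members higher, 0 lower (7 and 0 adjusted over the list alone). The p53 and cell death list had a camera adjusted p = 3.33e-04, and adjusted p = 0.669 with an estimated correlation. The 4 were Bbc3, Bcl2l11 and Bmf, which encode promoters of apoptosis of the Bcl2 family, at log2 fold changes of 2.80, 1.89 and 1.71, and Cflar, an inhibitor of death receptor signalling, at 1.11. Zinc finger genes named Zfp had a smaller median of 0.21, with 7 of 296 higher and 0 lower (15 and 3 adjusted over the list alone). The zinc finger list had a camera adjusted p = 3.64e-04, and adjusted p = 0.695 with an estimated correlation. Zfp217, Zfp712, Zfp36 and Zfp568 led this list, with log2 fold changes of 1.93, 2.24, 3.59 and 1.85. Noncoding transcripts moved the other way. The snoRNA and scaRNA genes had a median of −0.96 with 0 of 23 passing limma singly, including Scarna10 at −0.94 (SE 0.29), and were lower as a set. The snoRNA and scaRNA list had a camera adjusted p = 4.32e-08, and adjusted p = 0.669 with an estimated correlation. Nuclear and small noncoding RNAs had a median of −0.99 over 13 members, of which 0 passed over all genes and 3 were lower adjusted over the list alone. The nuclear noncoding list had a camera adjusted p = 1.13e-04, and adjusted p = 0.669 with an estimated correlation. Its members Airn and Kcnq1ot1, long antisense transcripts of imprinted loci, had log2 fold changes of −1.85 and −2.02 with limma adjusted p of 0.0759 and 0.0810, while Neat1 and Xist, which act in the nucleus, had −1.12 and −1.79. The microRNA host entries, rows with symbols that start with Mir and a digit, had a median of −0.96 over 24 members. Only Mir208b was lower, at −1.66 (SE 0.33), with 0 higher and 1 lower adjusted over the list alone. The microRNA host list had a camera adjusted p = 8.96e-07, and adjusted p = 0.669 with an estimated correlation.

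Mir208b lies in an intron of Myh7, the slow beta myosin heavy chain, and cannot be separated from it here. Myh7 itself was lower, at 179 ± 46.8 scaled CPM (SD, n = 2) in Cnot3 RIP and 537 ± 183 in control IgG RIP (log2 fold change −1.57, SE 0.31, limma adjusted p = 0.0423). It was the only member of the sarcomere list to pass, 1 of 27, and of the fetal and hypertrophy list, 1 of 19 (3 higher and 1 lower adjusted over the list alone), and neither list passed as a set, with camera adjusted p of 0.192 and 0.0554. The nuclear-encoded respiratory chain genes had a median log2 fold change of −0.14, which became 0.18 with scaling by library size only, −0.12 relative to all genes, and 0 of 75 passed singly (0 adjusted over the list alone). The respiratory chain list had a camera adjusted p = 0.0256, and adjusted p = 0.946 with an estimated correlation. That set call was lost without control IgG RIP replicate 2 (camera adjusted p = 0.446), turned without Cnot3 RIP replicate 2 (0.121) and was lost with scaling by library size only (0.282). The number of lists that were lower as a set, 4 here, was 8 without control IgG RIP replicate 1 and 9 without Cnot3 RIP replicate 1.

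Of the 36 lower genes, 13 were gamma protocadherins. These share their constant exons, so reads of 1 member can be assigned to another and the values of single members are uncertain. Pcdhga8, Pcdhgb8, Pcdhgb4, Pcdhga7, Pcdhgb5, Pcdhga4 and Pcdhga10 had log2 fold changes of −2.11, −2.02, −1.99, −1.99, −1.98, −1.97 and −1.94. Without control IgG RIP replicate 1 the values of the named protocadherins, Pcdhga9 included, lay between −1.64 and −1.38, and without control IgG RIP replicate 2 between −2.80 and −2.40. None passed limma without control IgG RIP replicate 1 or without Cnot3 RIP replicate 2. The named members of the cluster start between 37685210 and 37761801 on the plus strand of chromosome 18 and end together near 37841873. Outside the cluster, Lrrtm3, which encodes a synaptic adhesion protein, at chromosome 10, 63928472 to 64090277 on the minus strand, was lower at 9.21 ± 1.88 against 36.9 ± 14.3 scaled CPM (SD, n = 2; log2 fold change −1.93, SE 0.30, limma adjusted p = 0.0257). Tbrg3, a noncoding gene with no GENCODE coordinates, had −1.94 (limma adjusted p = 0.0497), −2.54 without Cnot3 RIP replicate 1 and −1.31 without Cnot3 RIP replicate 2. Placeholder symbols made up 14 of the 36 lower genes and 4 of the 200 higher ones.

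Cnot3, Atg7, Trp53 and Pdk4 had been fixed for reporting in advance, and 0 of these 4 passed limma against control IgG RIP. The Cnot3 transcript stood at 11.7 ± 3.61 scaled CPM (SD, n = 2) in Cnot3 RIP and 6.44 ± 0.592 in control IgG RIP (log2 fold change 0.81, SE 0.27, limma adjusted p = 0.155). Without Cnot3 RIP replicate 1 it passed, at 1.13 with a limma adjusted p of 0.0295. Atg7, which encodes an enzyme of autophagosome formation, had 0.65 (SE 0.23, limma adjusted p = 0.188), and Trp53, which encodes p53, had 0.69 (SE 0.31, limma adjusted p = 0.288). Pdk4, a kinase that restrains glucose oxidation, had 1.26 with an SE of 0.95 (limma adjusted p = 0.587), since its Cnot3 RIP libraries held 94.9 and 768 scaled CPM, and the value was 2.78 without Cnot3 RIP replicate 1 and −0.24 without replicate 2. Among the 11 CCR4-NOT subunits tested, 0 passed, with Cnot6 and Cnot8, which encode deadenylase catalytic subunits, at 0.92 and 1.13 and the ubiquitin ligase subunit Cnot4 at −0.52, and the list's median of 0.40 had a camera adjusted p of 0.215. Autophagy genes had a median of −0.01 over 39 members, 0 of which passed, and a camera adjusted p of 0.809, with Atg12, Atg4d and Atg4c at 0.79, 0.95 and 0.80.

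The other lists did not pass as sets, with camera adjusted p from 0.215 to 0.954. Single members passed in 2 of them. Adrb1, the main beta-adrenergic receptor of heart muscle, was higher at 59.4 ± 35.3 against 6.21 ± 1.03 scaled CPM (SD, n = 2; 8.45-fold), and Kcnj2, an inward rectifier potassium channel, at 240 ± 93.0 against 43.2 ± 15.7 (5.51-fold), 2 of the 38 ion channel and calcium handling genes (3 adjusted over the list alone). Among 229 solute carriers, Slc19a2, a thiamine transporter, Slc25a25, a mitochondrial carrier of ATP, and Slc35d1, a carrier of nucleotide sugars, were higher with log2 fold changes of 2.34, 2.15 and 1.64 (2 adjusted over the list alone). In the lists of cytosolic ribosomal proteins (50 tested), mitochondrial ribosomal proteins (75), fatty acid and glucose metabolism (54), cell cycle (33) and replication-dependent histones (15), 0 members passed limma over all genes or adjusted over the list alone. The same count of 0 over all genes held for markers of endothelium (20 tested), fibroblasts (20, of which 1 was higher adjusted over the list alone), smooth muscle and pericytes (12), leukocytes (21), erythroid cells and platelets (5) and nerve, fat, epicardium and skeletal muscle (8).

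**Figure D3:**
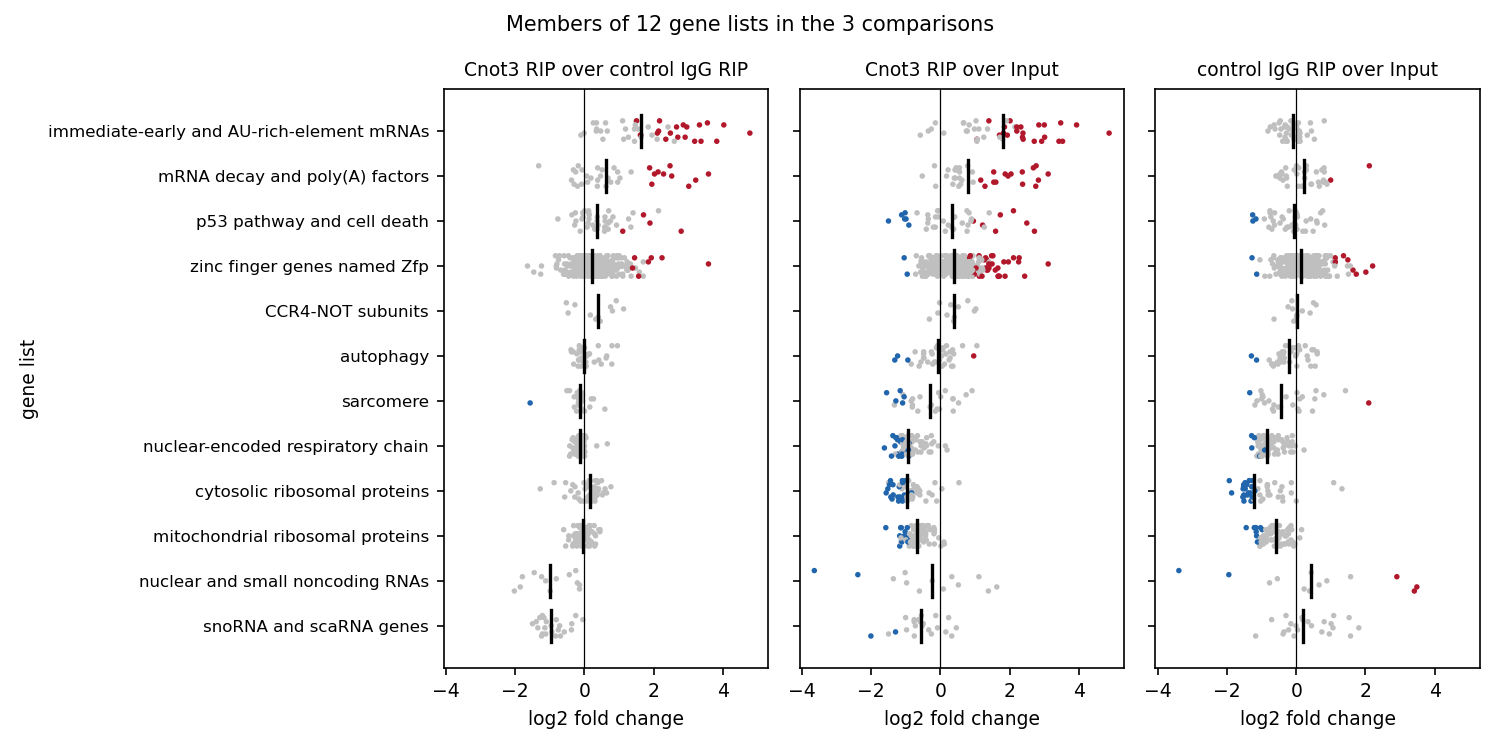
Log2 fold changes of the tested members of 12 gene lists in the 3 comparisons, with a black bar at each list's median. Red and blue points passed an adjusted p of 0.05, and the immediate-early list has medians of 1.64 and 1.81 over control IgG RIP and Input, while the respiratory chain and ribosomal protein lists have medians of −0.94 and −0.95 in Cnot3 RIP over Input, which become 0.14 and 0.07 with scaling by library size only.

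With the deposited CPM as they stand, the median log2 fold change of all genes over control IgG RIP was 0.30, and limma called 592 genes higher and 33 lower. The count of genes against control IgG RIP depended on single libraries. Limma called 0 genes without control IgG RIP replicate 1 (745 higher and 418 lower at an unadjusted p under 0.05, 0 by edgeR's quasi-likelihood test, smallest limma adjusted p = 0.128). It called 85 higher and 35 lower without control IgG RIP replicate 2, 1043 higher and 263 lower without Cnot3 RIP replicate 1, and 30 higher and 0 lower without Cnot3 RIP replicate 2 (680 and 367 unadjusted, 83 and 2 by edgeR's quasi-likelihood test). Unadjusted counts, here and below, are not calls. With no effect a share of 0.05 of the tested genes would pass on average, both directions together. All 200 higher and all 36 lower genes kept their sign in each of these fits, and in those without Input replicate 1 or 2. Genes called from these same libraries nearly had to keep their sign, here and in the comparisons below, so this adds little.

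The comparison of Cnot3 RIP with Input asked how the immunoprecipitate differed from the RNA of the lysate. Nfkbia again stood apart, at 29.4 times its Input level of 11.7 ± 5.64 scaled CPM (SD, n = 2; log2 fold change 4.88, SE 0.45, limma adjusted p = 0.00298). Hic2, a zinc finger repressor of transcription, at chromosome 16, 17233572 to 17263430, was 15.8-fold higher at 30.3 ± 6.33 against 1.67 ± 0.248 scaled CPM (log2 fold change 3.98, SE 0.26, limma adjusted p = 0.00108). Nr6a1, an orphan nuclear receptor, at chromosome 2, 38723370 to 38927688, was 13.7-fold higher. Rpph1, the RNA of ribonuclease P, at chromosome 14, 50807449 to 50807767, stood at 38.9 ± 10.6 scaled CPM in Cnot3 RIP and 481 ± 54.4 in Input, 0.0801 of the Input level (log2 fold change −3.64, SE 0.44, limma adjusted p = 0.00811). Limma called 762 genes higher and 321 lower, of which 693 and 244 differed by at least 2-fold, and 21 and 9 had placeholder symbols.

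Further genes that were higher against Input were Edn1, Id1, D5Ertd579e, Dusp1 and Ddit4, with log2 fold changes of 4.18, 4.11, 4.10, 3.94 and 3.72. The remaining lower genes by the same rule were the vault RNA Vaultrc5 at −2.67, the RNA of ribonuclease MRP, Rmrp, at −2.38, the RNA-binding protein gene Ybx1 at −2.09, the growth factor gene Igf2 at −1.73, the Hsp70 cofactor gene Bag1 at −1.70 and the ATP synthase subunit gene Atp5e at −1.62. Lars2, at −1.72 (SE 0.44, limma adjusted p = 0.0440), is uncertain because reads of ribosomal RNA are known to map to this gene. The list of immediate-early and AU-rich-element mRNAs had 24 of 45 members higher and 0 lower (33 adjusted over the list alone), with a median of 1.81. The immediate-early list had a camera adjusted p = 3.64e-16, and adjusted p = 0.509 with an estimated correlation. Decay and poly(A) factors had 15 of 35 higher and 0 lower (19 adjusted over the list alone), led by Tnrc6a at 2.69, Cpeb4 and Cpeb2, which control cytoplasmic poly(A) tails, at 2.77 and 2.37, and Zfp36l2 at 2.04 (median 0.79). The decay factor list had a camera adjusted p = 2.03e-11, and adjusted p = 0.509 with an estimated correlation. Zinc finger genes had 37 of 296 higher and 2 lower (49 and 2 adjusted over the list alone, median 0.40). The zinc finger list had a camera adjusted p = 7.83e-07, and adjusted p = 0.545 with an estimated correlation. Atg7 was the only autophagy gene that was higher, at 0.97 (SE 0.23, limma adjusted p = 0.0368), while the autophagosome coat genes Gabarap, Map1lc3a and Map1lc3b were lower at −1.23, −1.32 and −0.94 (2 higher and 4 lower adjusted over the list alone). In control IgG RIP over Input, 0 of 39 autophagy genes were higher and 2 were lower, Gabarap and Map1lc3a, so their loss was not particular to Cnot3 RIP.

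Genes of energy production and protein synthesis lay below the bulk of genes in Cnot3 RIP over Input. This was not particular to Cnot3 RIP. In control IgG RIP over Input the respiratory chain, cytosolic ribosomal, mitochondrial ribosomal and histone lists had medians of −0.83, −1.23, −0.60 and −0.87. The nuclear-encoded respiratory chain had 26 of 75 members lower and 0 higher (61 lower adjusted over the list alone), led by Atp5e, Ndufa2, Ndufb5 and Ndufb11, and its median of −0.94 became 0.14 with scaling by library size only, which was −0.88 relative to all genes. The respiratory chain list had a camera adjusted p = 1.05e-23, and adjusted p = 0.509 with an estimated correlation. Cytosolic ribosomal proteins had 19 of 50 lower and 0 higher (35 adjusted over the list alone), with Rps20, Rps2 and Rpl23 among them, and a median of −0.95 that became 0.07 with library size only, −0.95 relative to all genes. The cytosolic ribosomal list had a camera adjusted p = 1.86e-17, and adjusted p = 0.187 with an estimated correlation. Mitochondrial ribosomal proteins had 11 of 75 lower, 0 higher (23 adjusted over the list alone), and a median of −0.66 that became 0.37, −0.65 relative to all genes. The mitochondrial ribosomal list had a camera adjusted p = 1.63e-16, and adjusted p = 0.509 with an estimated correlation. Replication-dependent histones, whose mRNAs end in a stem-loop in place of a poly(A) tail, had a median of −1.15 with 1 of 15, Hist3h2a, lower (7 adjusted over the list alone), and this median stayed below 0 under library size only at −0.23. The histone list had a camera adjusted p = 5.36e-06, and adjusted p = 0.594 with an estimated correlation. Of 27 sarcomere genes, 5 were lower (6 adjusted over the list alone), with Myoz2, Myl2, Myl3 and Csrp3 at −1.55, −1.28, −1.16 and −1.09, and the list's median of −0.29 became 0.79 with library size only, −0.23 relative to all genes. The sarcomere list had a camera adjusted p = 0.00393 (0.106 with library size only), and adjusted p = 0.810 with an estimated correlation. In control IgG RIP over Input the sarcomere median was −0.45, with Myh7 higher and Myoz2 lower (camera adjusted p = 0.0904).

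Smaller lists completed the comparison with Input. Metabolism genes had 1 of 54 higher, Ppargc1b, a coactivator of mitochondrial gene expression, and 3 lower, Ucp2, Etfb and Aldoa (1 and 4 adjusted over the list alone), with a median of −0.40 that became 0.68 with library size only, −0.34 relative to all genes. The metabolism list had a camera adjusted p = 5.76e-04 (0.642 with library size only, 0.0847 without Cnot3 RIP replicate 1, 0.165 without Input replicate 2), and adjusted p = 0.810 with an estimated correlation. The snoRNA and scaRNA genes had 2 of 23 lower, among them Scarna10 (2 adjusted over the list alone), and a median of −0.55 that became 0.25 with library size only, −0.77 relative to all genes. The snoRNA and scaRNA list had a camera adjusted p = 0.00175 (0.634 without Input replicate 1), and adjusted p = 0.810 with an estimated correlation. Leukocyte markers had 1 of 21 lower, the macrophage lysozyme gene Lyz2 (0 adjusted over the list alone), with a median of −0.50 that became 0.50, −0.52 relative to all genes. The leukocyte list had a camera adjusted p = 0.0156 (0.406 without Cnot3 RIP replicate 2, 0.264 without Input replicate 2), and adjusted p = 0.810 with an estimated correlation. Nerve, fat, epicardial and skeletal muscle markers had 1 of 8 lower, skeletal actin Acta1, which heart muscle also makes (2 adjusted over the list alone), with a median of −0.67 that became 0.29, −0.73 relative to all genes. The nerve and fat list had a camera adjusted p = 0.0132, and adjusted p = 0.509 with an estimated correlation. The p53 and cell death list did not pass as a set (camera adjusted p = 0.363), with 7 of 41 higher and 6 lower (11 and 7 adjusted over the list alone), among them Cflar, Bcl2l11 at 2.50 and Bbc3 at 2.72 on the higher side and Cycs, cytochrome c, at −1.50 on the lower side. In control IgG RIP over Input 0 of these 41 genes were higher and 3 were lower, Cycs among them.

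Lists that did not pass as sets against Input had camera adjusted p from 0.158 to 0.998. Among them 0 of 11 CCR4-NOT subunits passed limma, with a median of 0.39, 0 adjusted over the list alone, and Cnot3 itself at 0.99 (limma adjusted p = 0.0525). Adrb1 and Kcnj2 were higher against Input as well, at 3.12 and 2.59. Myocd, a coactivator of muscle genes, was higher at 1.73, and Nppa and Acta1 were lower in the fetal and hypertrophy list (1 and 2 adjusted over the list alone). Of 229 solute carriers, 12 were higher and 2 lower (5 and 2 adjusted over the list alone).

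Scaling mattered for this comparison, since the median log2 fold change of all genes was 0.06 with TMM scaling and 1.02 with the deposited CPM as they stand, where limma called 7752 genes higher and 7 lower, so that the higher share moved from 70.4% to 99.9%. The counts were 466 higher and 196 lower without control IgG RIP replicate 1, 519 and 164 without control IgG RIP replicate 2, 1461 and 509 without Cnot3 RIP replicate 1, 158 and 21 without Cnot3 RIP replicate 2, 98 and 10 without Input replicate 1 and 10 and 2 without Input replicate 2, and all 762 and 321 genes kept their sign in these 6 fits.

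Genes that were higher in Cnot3 RIP than in both control IgG RIP and Input numbered 195, which is 97.5% of the 200 genes that were higher against control IgG RIP. They were ranked by the smaller of their fold changes, among genes with a mean of at least 10 CPM in Cnot3 RIP and no placeholder symbol. The leading genes were Nfkbia, Edn1, Id1, D5Ertd579e, Dusp1, Ddit4, F3 and Fos. Tnf and Lif lay below that level, at 4.71 and 4.85 scaled CPM in Cnot3 RIP, and were not selected by the naming rule. Their log2 fold changes were 3.83 and 3.56 over control IgG RIP and 3.53 and 3.48 over Input. Their means were only 0.0968 and 0.249 scaled CPM in control IgG RIP and 0.231 and 0.211 in Input. These means lie below the 0.25 added before log2 was taken, so the size of the fold changes depends on that setting and is uncertain. Fos, the immediate-early transcription factor gene at chromosome 12, 85473890 to 85477273, stood at 25.3 ± 5.79 scaled CPM in Cnot3 RIP, 2.78 ± 2.54 in control IgG RIP and 2.36 ± 1.63 in Input (SD, n = 2), or 10.3-fold and 10.8-fold higher. F3 was 13.3-fold and 11.9-fold higher. Of the 195 genes, 4 had placeholder symbols, and all 195 differed by at least 2-fold in both comparisons. The comparisons share the Cnot3 RIP libraries, so part of the excess may come from the shared libraries: 11.7 genes were expected for independent lists, and 50 simulations with no effect gave at most 0 by limma, against 1026 observed and 47.6 simulated on average at an unadjusted p under 0.05. These simulations held no differences in any comparison. They cannot show how much the shared libraries add to the overlap where differences exist. The 195 became 0 without control IgG RIP replicate 1 (where limma and edgeR's quasi-likelihood test called 0 against control IgG RIP and 745 genes were higher there at an unadjusted p under 0.05), 79 without control IgG RIP replicate 2, 889 without Cnot3 RIP replicate 1, 28 without Cnot3 RIP replicate 2, 72 without Input replicate 1 and 10 without Input replicate 2.

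The comparison of control IgG RIP with Input measured the background of the procedure. Gamma protocadherins led it, with Pcdhga8 at 38.2 ± 21.7 scaled CPM (SD, n = 2) in control IgG RIP and 1.39 ± 0.0105 in Input, 21.5-fold (log2 fold change 4.43, SE 0.36, limma adjusted p = 0.00299), with the same limit of shared exons as above. Lrrtm3 was 13.6-fold higher and its relative Lrrtm2, at chromosome 18, 35209003 to 35215024, was 12.4-fold higher. Rpph1 stood at 0.0952 of its Input level (log2 fold change −3.39, SE 0.44, limma adjusted p = 0.00902) and Rmrp at 0.259. Limma called 336 genes higher and 194 lower, of which 321 and 171 differed by at least 2-fold, and 99 and 6 had placeholder symbols.

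The remaining protocadherins by the same rule were Pcdhgb5, Pcdhga9, Pcdhga6, Pcdhga4 and Pcdhga10, with log2 fold changes of 3.97, 3.92, 3.72, 3.64 and 3.62. Lower genes were Vaultrc5 at −2.12, Ybx1 at −1.75, Igf2 at −1.67, Bag1 at −1.58 and the ribosomal protein genes Rps14 and Rplp0, both at −1.54. Cytosolic ribosomal proteins had 23 of 50 members lower and 0 higher (35 and 1 adjusted over the list alone) and a median of −1.23, which stayed below 0 at −0.51 with scaling by library size only. The cytosolic ribosomal list had a camera adjusted p = 4.22e-19, and adjusted p = 0.160 with an estimated correlation. Of the respiratory chain genes, 6 of 75 were lower and 0 higher (50 adjusted over the list alone), with a median of −0.83 that stayed at −0.07 with library size only. The respiratory chain list had a camera adjusted p = 1.28e-18, and adjusted p = 0.816 with an estimated correlation. Mitochondrial ribosomal proteins had 9 of 75 lower and 0 higher (24 adjusted over the list alone) and a median of −0.60 that became 0.13 with library size only, −0.57 relative to all genes. The mitochondrial ribosomal list had a camera adjusted p = 1.40e-14, and adjusted p = 0.816 with an estimated correlation. Histones had a median of −0.87, −0.24 with library size only, with 0 of 15 passing limma over all genes and 5 lower adjusted over the list alone. The histone list had a camera adjusted p = 1.99e-04, and adjusted p = 0.859 with an estimated correlation.

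Among nuclear and small noncoding RNAs, Airn, Kcnq1ot1 and Xist were higher in control IgG RIP than in Input at log2 fold changes of 3.49, 3.41 and 2.91, and Rmrp and Rpph1 were lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.374). Airn and Kcnq1ot1 overlap genes on the opposite strand, and since the strand of the counting is not given in the sources used here, their reads cannot be told apart from those of their partners. The microRNA host entries had 3 of 24 higher, among them Mir208b at 1.92, and 1 lower (8 and 1 adjusted over the list alone, median 0.72). The microRNA host list had a camera adjusted p = 0.00342 (0.501 with library size only), and adjusted p = 0.816 with an estimated correlation. Immediate-early and AU-rich-element mRNAs had 0 of 45 passing limma over all genes or adjusted over the list alone and a median of −0.09 (camera adjusted p = 0.374). Of decay factors, 2 of 35 were higher, Dcp1b, a decapping cofactor, and Pan2, a deadenylase (3 adjusted over the list alone, camera adjusted p = 0.0672). Metabolism genes had a median of −0.36 that became 0.40 with library size only, −0.30 relative to all genes, and 0 of 54 passing. The metabolism list had a camera adjusted p = 7.34e-04 (0.153 with library size only, 0.400 without control IgG RIP replicate 2, 0.164 without Input replicate 2), and adjusted p = 0.995 with an estimated correlation. The fetal and hypertrophy genes had 1 of 19 higher, Myh7, and 2 lower, Nppa, the atrial natriuretic peptide gene, at −1.24 and Acta1 at −1.02 (1 and 3 adjusted over the list alone, median −0.47, which became 0.28 with library size only, −0.42 relative to all genes). That list had a camera adjusted p of 0.0416, which was 0.153 with library size only, 0.117 without control IgG RIP replicate 1, 0.0763 without Input replicate 1 and adjusted p = 0.816 with an estimated correlation. The number of lists that were higher as a set, 1 here, was 3 without Input replicate 1.

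With the deposited CPM as they stand, the median of all genes in control IgG RIP over Input was 0.70 (0.007 with TMM scaling), and limma called 4383 genes higher and 10 lower, so that the higher share moved from 63.4% to 99.8%. The counts were 16 higher and 4 lower without control IgG RIP replicate 1, 77 and 5 without control IgG RIP replicate 2, 509 and 386 without Cnot3 RIP replicate 1, 509 and 373 without Cnot3 RIP replicate 2, 121 and 5 without Input replicate 1 and 41 and 3 without Input replicate 2, with all 336 and 194 genes keeping their sign.

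Transcript features were compared with the log2 fold change across 12349 protein-coding genes, as 21 Spearman correlations given without p-values, since genes are not independent replicates. Genes with longer 3′ UTRs lay higher in Cnot3 RIP over control IgG RIP (rho = 0.269, and 0.163 and 0.238 with the replicate 1 or the replicate 2 libraries alone), and the median log2 fold change was −0.11 in the tertile of genes with the shortest 3′ UTRs and 0.14 in the tertile with the longest. The number of AUUUA motifs per kb of 3′ UTR had rho = 0.157, which was 0.0561 with the replicate 1 libraries alone. Transcript length, coding length and mean level had rho of 0.102, −0.116 and 0.159, and each of these took the opposite sign in 1 set of libraries, −0.00903 and −0.0532 for transcript length and level with replicate 1 alone and 0.0271 for coding length with replicate 2 alone. Among 7035 genes with a mean of at least 5 CPM the rho of level was 0.0107 and that of coding length −0.178, and coding length had −0.201 with replicate 1 alone. Against Input, long transcripts lay higher in both immunoprecipitates, with rho of 0.504 for Cnot3 RIP and 0.471 for control IgG RIP, and for coding length the values were 0.435 and 0.579. For 3′ UTR length they were 0.319 and 0.139, the latter 0.0510 with the replicate 1 libraries alone. Transcript GC content had rho of −0.0967, −0.167 and −0.108 and 3′ UTR GC content −0.0966, −0.172 and −0.107 in the 3 comparisons. Against control IgG RIP both GC values also took the opposite sign with the replicate 1 libraries alone, at 0.0156 and 0.00364. With those libraries the values against Input were −0.0260 and −0.0357 for transcript GC content and −0.0466 and −0.0378 for 3′ UTR GC content, in Cnot3 RIP and control IgG RIP.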

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

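The alternatives chosen after seeing the data were pseudocounts of 0.05 and 1, leaving Rn45s, Lars2 and Mir6236 out, summing the gamma protocadherins into 1 gene and the crossed block. The quasi-likelihood test of edgeR was the test named in the design, and limma took its place after the unit of the table was seen. RLE size factors, robust empirical Bayes and a pseudocount of 0.05 left each of the 7 counts of genes within 1.5 times its reported value. The cause was not tested for the changes below, except that fewer samples or other filters change the number of libraries and genes tested. Counts are given as higher and lower. The setting without mitochondrially encoded genes changed nothing because the table used here held none, so it has no values.

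Against control IgG RIP (200 and 36) the counts were 425 and 136 at an adjusted p of 0.10, 592 higher with library size only, 34 and 1 with no low-count filter, 573 and 162 with DESeq2, 713 and 303 with edgeR's exact test, 95 and 17 with only the 2 groups compared, 65 lower with a pseudocount of 1 and 21 lower with the protocadherins summed. Against Input (762 and 321) they were 1304 and 817 at an adjusted p of 0.10, 7752 and 7 with library size only, 718 lower with upper quartile scaling, 445 and 103 with no filter, 570 lower with the stricter filter, 523 lower with DESeq2, 1218 and 648 with edgeR's exact test and 308 higher without Rn45s, Lars2 and Mir6236. For control IgG RIP over Input (336 and 194) they were 803 and 656 at an adjusted p of 0.10, 4383 and 10 with library size only, 102 lower with no filter, 132 and 129 with the stricter filter, 665 and 476 with edgeR's exact test, 134 and 88 with limma-voom, 571 and 431 with only the 2 groups compared, 220 and 119 with edgeR's quasi-likelihood test and 130 higher without Rn45s, Lars2 and Mir6236. Genes higher in both (195) numbered 391, 591, 34, 477, 564 and 95 at an adjusted p of 0.10, with library size only, no filter, DESeq2, edgeR's exact test and only the 2 groups compared.

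Leaving out each library in turn gave 0 to 1043 higher and 0 to 263 lower against control IgG RIP, where a count of 0 in limma came with at least 680 higher and 367 lower genes at an unadjusted p under 0.05 and with 0 and 2 lower genes by edgeR's quasi-likelihood test without control IgG RIP replicate 1 and Cnot3 RIP replicate 2. The ranges were 10 to 1461 and 2 to 509 against Input, 16 to 509 and 3 to 386 for control IgG RIP over Input, and 0 to 889 for genes higher in both. Lists lower against control IgG RIP ranged from 3 to 9 and lists higher in control IgG RIP over Input from 1 to 3. The unadjusted counts include the genes that would pass with no effect. The log2 fold change of Pdk4 ranged from −0.24 without Cnot3 RIP replicate 2 to 2.78 without Cnot3 RIP replicate 1. The camera p of the nuclear-encoded respiratory chain in Cnot3 RIP over control IgG RIP ranged from 5.34e-08 without Cnot3 RIP replicate 1 to 0.303 without control IgG RIP replicate 2, and was 0.0541 in the opposite direction without Cnot3 RIP replicate 2.

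The replicate numbers were not taken as pairs, since the labels give no shared source and deviations from the group means of libraries with the same number correlated at −0.317 between Cnot3 RIP and control IgG RIP, 0.339 between Cnot3 RIP and Input and −0.327 between control IgG RIP and Input. With a replicate block the lower counts were 93, 166 and 77 in the order of the comparisons above, and the fetal and hypertrophy list in control IgG RIP over Input had a camera adjusted p of 0.0580. A replicate block with the control IgG RIP numbers crossed gave 760 and 305, 1576 and 922, 1050 and 820, and 636 higher in both, and 1 of the 4 genes fixed in advance passed limma against control IgG RIP there.

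With an estimated correlation 0 lists were higher and 0 lower in each comparison, by camera's test, against 4 and 4, 3 and 9 and 1 and 6 with the preset one. Camera on ranks gave 2 lists higher in control IgG RIP over Input. Of 59 genes named in Cnot3 RIP over control IgG RIP, 40 had a call to lose. Of these 40, 27 lost it with no low-count filter and 13 with only the 2 groups compared. All were lost without control IgG RIP replicate 1 and a part without Cnot3 RIP replicate 2, fits that leave 1 library in a group. In that comparison no sign of the 59 genes changed but that of Pdk4. Correlations with features for Cnot3 RIP over control IgG RIP, with replicate 1 alone, were −0.00903 for transcript length, 0.163 for 3′ UTR length, 0.0561 for AUUUA and −0.0532 for level, and with replicate 2 alone 0.0271 for coding length. Over Input those of Cnot3 RIP were 0.443 (replicate 1) and 0.575 (mean CPM 5) for transcript length, 0.225 (replicate 1) for 3′ UTR length and 0.374 (replicate 2) for coding length. For control IgG RIP over Input they were 0.361, 0.412 and 0.613 for transcript length and 0.513, 0.431 and 0.697 for coding length with replicate 1, replicate 2 and mean CPM 5.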

Other observations

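The classes of genes and the search for 3′ UTR heptamers were examined only after the data were seen, and the test of let-7 seed matches was chosen after its result was seen. Nearly all genes higher in Cnot3 RIP than in control IgG RIP encoded proteins, 199 of 200 (99.5%), against 95.4% of all genes tested. Among these 200, 0 were noncoding, which allows up to 1.83%. Of the genes higher in control IgG RIP than in Input, 94 of 336 (28.0%, 23.2 to 33.1) were noncoding, against 3.84% of all genes tested. The AUUUA motif stood in the 3′ UTR of 182 of 199 enriched mRNAs (91.5%, 86.7 to 94.9) and of 70.8% of 12349 tested mRNAs, a share that long 3′ UTRs raise by themselves.

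All 16126 heptamers were ranked by the t statistic of the difference in Cnot3 RIP over control IgG RIP between mRNAs with and without the heptamer in the 3′ UTR. The trend with 3′ UTR length, 3′ UTR GC content, transcript length and level was removed first. TATTTTT ranked first with a difference of 0.16 on the log2 scale over 5194 mRNAs. The AU-rich heptamers TATTTAT and ATTTATT ranked 9 and 13. Heptamers made mostly of T ranked above both, with TTTTTTA, ATTTTTT, TTTTTAT and TTTTTTT at 2, 3, 4 and 5. These ranks therefore do not set the AUUUA motif apart from stretches rich in T. Of 14 seed matches of microRNAs abundant in heart, 3 ranked 100 or better, with miR-30 at 22, miR-26 at 87 and miR-1 at 89, and the other 11 ranged from 503 to 13626. In control IgG RIP over Input the matches of miR-30, miR-26 and miR-1 ranked 291, 3878 and 79, so those of miR-30 and miR-1 also lay high in the background. The 4 matches of microRNAs of other tissues ranged from 908 to 15712. The Pumilio site TGTAAAT ranked 50.

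Immediate-early and AU-rich-element mRNAs lay higher in Cnot3 RIP than in control IgG RIP in each pairing of single libraries, with list medians of 1.88, 1.21, 2.21 and 1.58. The list's median differed by −0.34 between the Input libraries (replicate 2 minus replicate 1), but the labels do not say which animals stand behind which libraries, so different transcript levels between the hearts stay open. A trend with 3′ UTR length, GC content, transcript length and level is argued against as the whole cause by a median of 1.65 after its removal, against 1.64 before. A single library is argued against by a median of 1.52 with Cnot3 RIP replicate 1 alone. Binding of these mRNAs by Cnot3 or its partners may also contribute and was not tested, since no independent antibody or Cnot3-deficient lysate was measured.

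The let-7 seed match CTACCTC was found in 46 of 199 enriched mRNAs (23.1%, 17.4 to 29.6) and in 10.7% of all tested. The heptamer ranked 4523 in control IgG RIP over Input, but the control IgG RIP libraries enter the comparisons with opposite signs, so background of the immunoprecipitation stays open. In Cnot3 RIP over control IgG RIP it ranked 74, below AU-rich heptamers and the miR-30 match and above the other seed matches searched, so a part of let-7 itself is left open. Removing the trend with 3′ UTR length, GC content, transcript length and level took the difference from 0.17 to 0.0854 on the log2 scale, so the trend accounted for part of the difference. What gave the remaining difference was not tested.

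The 36 genes lower in Cnot3 RIP than in control IgG RIP were all among the genes higher in control IgG RIP than in Input, where their median log2 fold change was 3.35, and 35 of them also lay above 0 in Cnot3 RIP over Input, with a median of 1.41. The first 2 sets of calls share the control IgG RIP libraries, so part of the excess may come from the shared libraries: 0.930 genes were expected for independent lists, and 50 simulations gave at most 0 by limma, with 642 observed and 52.0 simulated on average at an unadjusted p under 0.05. Since the simulations held no differences, the part that comes from the shared libraries stays unknown. With the gamma protocadherins summed into 1 gene 21 genes were lower, a count that 23 of the 36 lying outside the cluster had largely fixed, so reads shared within the cluster stay open for its 13 members. Noncoding transcripts made up 41.7% of the 36 (25.5 to 59.2) against 3.84% of genes tested. A candidate explanation is noncoding RNA that the control retained more. Among genes higher in Cnot3 RIP than in Input, 10 of 762 (1.31%, 0.631 to 2.40) were noncoding, below the 3.84% of genes tested. Of the 36 genes, 17 were called higher in Cnot3 RIP than in Input. The 500 noncoding genes tested had median log2 fold changes of 0.79 in control IgG RIP and 0.16 in Cnot3 RIP over Input. Protein-coding genes had −0.0099 and 0.056. A share of calls says little about a whole class, so how far retention by both immunoprecipitates extends stays open.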
